A study of Mus musculus with 40 samples.

How the data were processed

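Gene expression was measured on 40 single-colour mouse arrays of 45101 probe sets, from the spiral ganglion (SG, 22 arrays) and the vestibular ganglion (VG, 18 arrays) at 6 stages. The deposited values are signal intensity on a linear scale, one column per array, and no array file from the scanner was analysed here. How the authors summarised probes and scaled the arrays is not given in the sources used here. Values ran from 0.38 to 15109, with 3.09% exactly 1, and array medians ran from 139.63 to 173.31 (157.7 over all values), so the arrays were already near a common scale and were not scaled again. Per the labels' protocols, ganglia were pooled, RNA was amplified before labelling, E12 and E13 ganglia of both kinds and the later inferior VG were microdissected from 1 reporter line, and SG neurons from E16 on were sorted by GFP from dissociated cochleae of other crosses, with trypsin added from P0. Replicate numbers are those of the labels, and nothing in them ties an SG array to a VG array or a stage to another.

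Probe sets were assigned by the gene symbols of the array's annotation, checked by gene identifier against a mouse gene table built on GRCm38.p6, which was used for names only. Of the probe sets, 64 are controls, 34945 have 1 gene symbol (34741 matched in the gene table), 932 have several and 9160 have none. A gene was represented by its probe set with the highest mean over the 40 arrays, which gave 18193 genes. Intensities were taken to log2 after adding 16, and a gene was tested if its probe set exceeded the median of all values (log2 7.44) in at least 3 arrays, leaving 13521 genes with 4672 left out as dim. Probe sets without 1 symbol were kept apart. Genes such as Mafb and Mpz have no probe set under their symbol.

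Group means of the 12 groups were fitted to all 40 arrays with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with version 1.17.8 of the data.table package. The 20 contrasts are SG minus VG at each stage (6), each successive stage change and P15 minus E16 within each ganglion (12), and the difference between the ganglia in the E13 minus E12 and the P15 minus E16 change (2). Adjusted p-values are Benjamini-Hochberg over the tested genes of a contrast, and a gene is called below 0.05. Model, contrasts, thresholds, gene lists, the rule for naming genes and the alternatives were set before the data were examined, except the fit without 3 sorted arrays and the tests named as later choices in the closing section. No covariate was available: the labels name no batch or date.

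The rule for named genes takes Gata3, Mafb and Tlx3, and in each contrast the 3 called genes with the largest change each way whose groups do not overlap (6 each way for SG minus VG at E12 and E13 and for P15 minus E16 within a ganglion). It adds the called members with the largest changes in each list that passed, up to 3 per list, and up to 6 for guidance and adhesion in SG minus VG, and all genes called the same way at 6 stages when few. The 23 lists were written from general knowledge: otic neuron identity, ganglion-enriched transcription factors, axon guidance, cell adhesion, presynaptic genes, glutamate receptors, voltage-gated channels, growth factor signalling, proliferation, Schwann and satellite cells, hair cells, otic epithelium, mesenchyme, endothelium, macrophages, erythroid cells, brain, dissociation and immediate early genes, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, and type I and type II SG neurons. Lists were tested with camera at a preset correlation of 0.01, beside an estimated correlation, adjusted over the lists of a contrast. List members were also adjusted over the list alone. Overlaps of calls are given with the number that independent lists would share. Small samples of single values were compared with exact two-sided permutation tests.

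Alternatives were only the arrays compared, quantile scaling, centring, an offset of 1, no dim filter, a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets that can bind several transcripts, no intensity trend, array weights, a 2-fold minimum, replicate blocks and each array left out in turn. Other splits of the arrays were fitted the same way. On simulated data with log2 changes of 0.5, 1 and 2 added to 67, 67 and 66 of 13521 genes, the fit recovered 14, 33 and 62 at E12, 20, 40 and 61 at P6, 11, 43 and 61 for P0 minus E16 in the VG, and 4, 24 and 55 for the later difference between ganglia. It called 0, 27, 5 and 11 unchanged genes, a share of calls above the threshold at P6 and for that difference. Within groups arrays correlated at 0.990 to 0.997 at E12 and E13, 0.836 to 0.989 in sorted SG groups and 0.966 to 0.993 in later VG groups, and the median SD of a gene was 0.065 to 0.133, 0.229 to 0.280 and 0.111 to 0.182. Plots used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.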

Results

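The spiral ganglion (SG) carries hearing and the vestibular ganglion (VG) carries balance from the inner ear to the brain. The 40 arrays compare the 2 ganglia of mice at E12, E13, E16, P0, P6 and P15, with 3 arrays per group in the VG and in the E12 and E13 SG, and 4 arrays per group in the SG from E16 to P15. E12 and E13 ganglia and the later VG were dissected from a Tlx3-Cre reporter line, while SG samples from E16 to P15 are GFP neurons sorted from Mafb-GFP crosses. Each SG to VG difference after E13 therefore holds ganglion, strain, sorting and enzyme treatment together. The samples are pools, and the p-values measure spread between these arrays. Values are log2 changes, and a value after ± is a standard error unless marked SD. Where the lower group mean lies under log2 7.44, the limit for dim probe sets, as for Fgf5, Kcnj3, Prdm8, Neurod6 and Glra2 at E12 and E13 and Nwd2 at E13, the size of a difference also depends on the offset added before taking logs.

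Gata3, a zinc-finger factor needed for SG neuron development, was called higher in the SG from E16 onward and was not called at E12 or E13. Its log2 difference from the VG was 0.49 at E12 (adjusted p = 0.833) and 1.20 at E13 (adjusted p = 0.134), against 4.13 ± 0.47 at E16 and 3.62 ± 0.47 at P0. The 2 early values had adjusted p = 1.17e-09 and 2.31e-05 when the fit held only the 6 arrays compared. At P6 the difference was 2.15, with adjusted p = 0.0588 when only the 7 arrays compared were fitted, and at P15 it was 3.27 ± 0.47 (adjusted p = 9.42e-07). In the VG, Gata3 fell by a log2 change of 2.36 from E13 to E16 (adjusted p = 0.000552), and in the SG it fell by 2.18 from E16 to P15 (adjusted p = 0.000101). Tlx3, the homeobox gene whose Cre marks the VG in these mice, was lower in the SG at E12 (log2 -1.96 ± 0.27, adjusted p = 6.77e-06) and was not called at E13, E16, P0 or P6. With only the arrays compared it was called at E13 (-0.52, adjusted p = 0.0112) and not at P15 (adjusted p = 0.112). Tlx3 fell in the VG from E12 to E13 (log2 -1.44, adjusted p = 0.000608). Its P15 difference of 0.63, between overlapping groups whose means lie under log2 7.44, was called, and was not without SG array 1 or 4 (0.49, 0.47) or VG array 2 or 3 (0.59, 0.62). Mafb, the gene behind the GFP used for sorting, has no probe set with its symbol here and was not analysed.

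**Figure D1:**
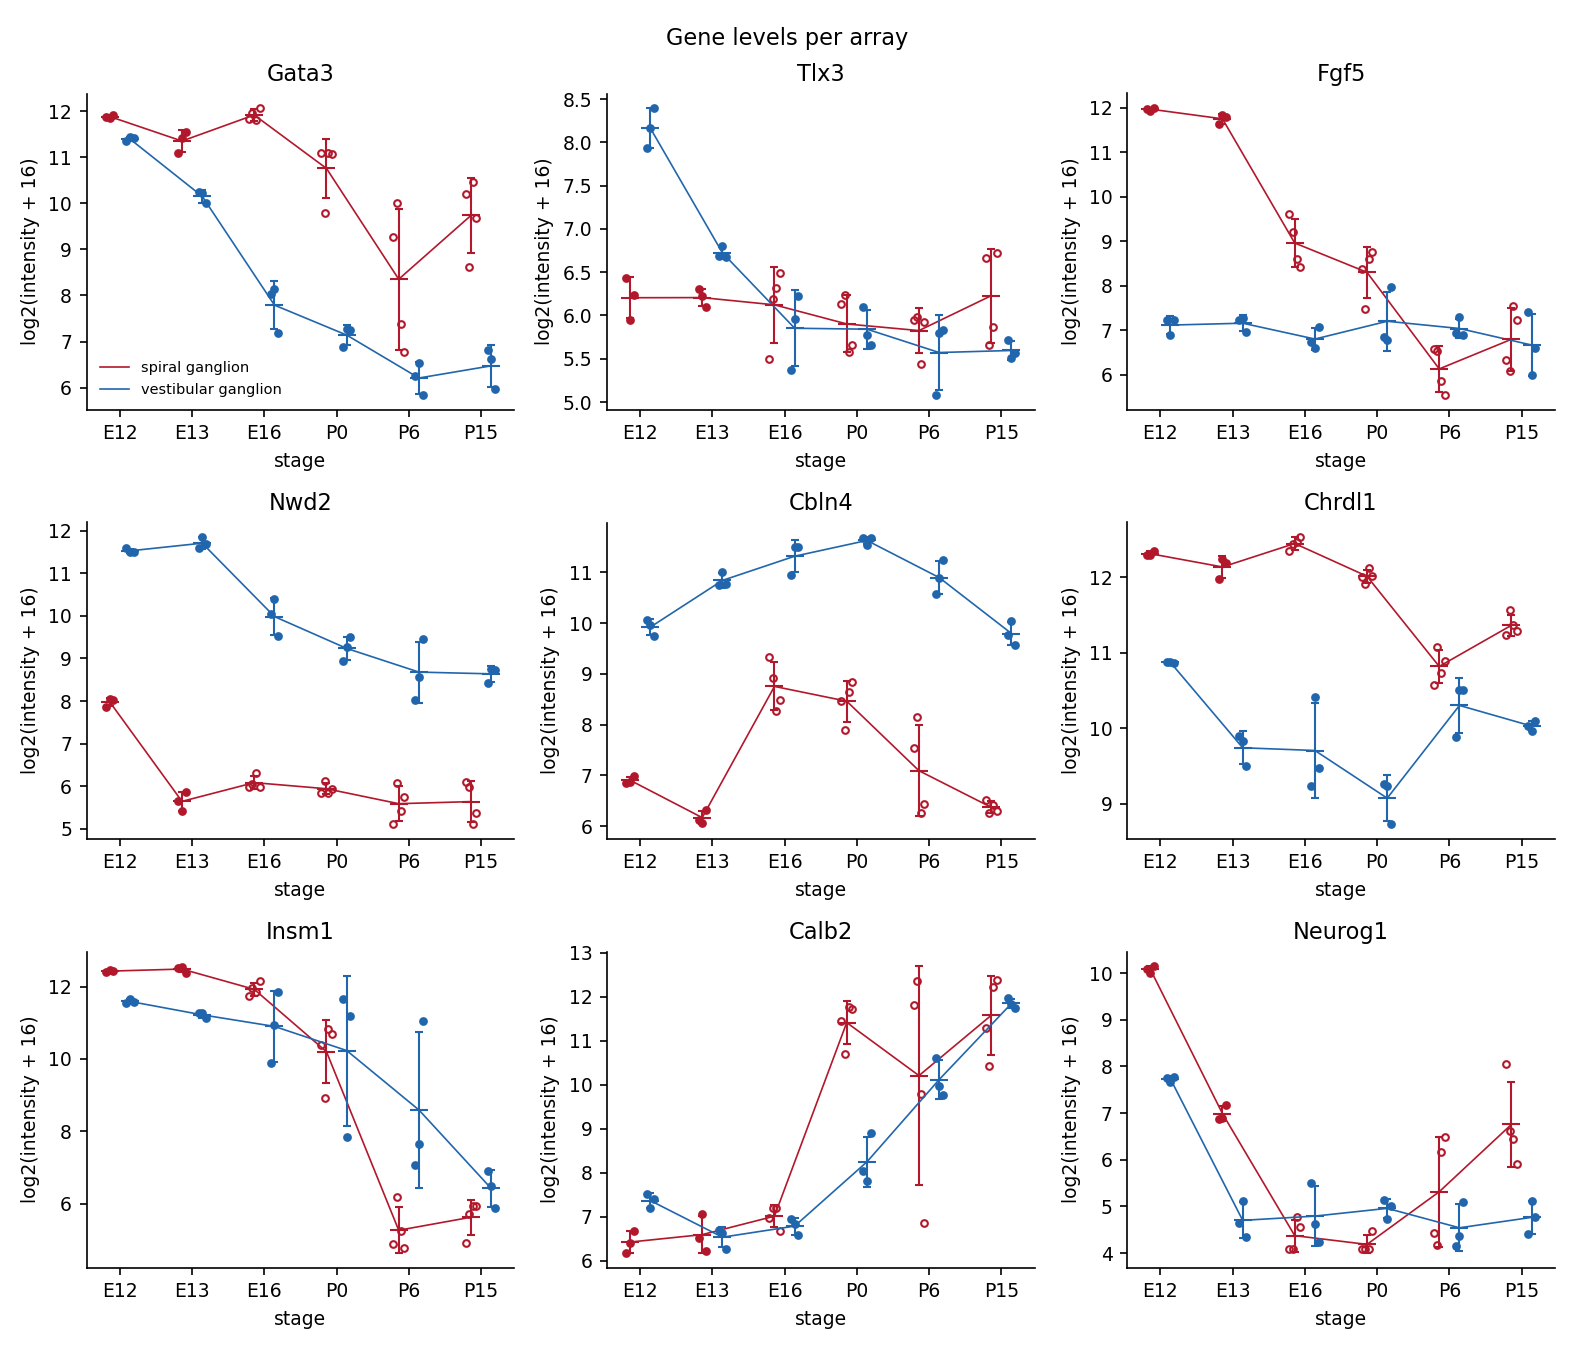
Expression of 9 genes by stage, as log2 of intensity plus 16, in SG and VG: points are arrays (open points are sorted SG samples), lines join group means and error bars are SD. The SG minus VG difference of Gata3 is 1.20 at E13 and 4.13 at E16, and that of Fgf5 is 4.85 at E12.

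At E12 Fgf5, a secreted fibroblast growth factor, was higher in the SG (log2 4.85 ± 0.38, adjusted p = 4.98e-11; 11.97 ± 0.03 (SD, n = 3) against 7.12 ± 0.20 (SD, n = 3)). Kcnj3, a G-protein-gated potassium channel, was higher by 4.34 (adjusted p = 1.18e-06), with the transcription regulators Prdm8 (4.21), Insm2 (3.71), Neurod6 (3.48) and Mab21l1 (3.48). The glycine receptor subunit Glra2 was lower by 4.30 (adjusted p = 4.37e-05), as were the aldehyde dehydrogenase Aldh1a7 (-4.27), the G-protein regulator Rgs8 (-4.21), Vwc2l (-4.20), the protease Corin (-4.19) and Kazald1 (-4.12). In total 626 genes were called, 268 higher and 358 lower in the SG. Of 23 ganglion-enriched transcription factors, 1 was higher, 4 lower and 18 not called (1 and 6 adjusted over the list alone), with Onecut1 (-3.52) and Tbx3 (-2.18) lower and Irx3 (2.00) higher in the SG (adjusted p = 0.003, and adjusted p = 0.747 with an estimated correlation). Of 38 voltage-gated channel genes, 2 were higher, 6 lower and 30 not called (2 and 12 adjusted over the list alone), Kcnd3 by -2.13 (adjusted p = 0.00183, and adjusted p = 0.747 with an estimated correlation). Of 35 presynaptic genes, 1 was higher, 1 lower and 33 not called (1 and 3 adjusted over the list alone, median log2 -0.31, adjusted p = 0.0345, and adjusted p = 0.839 with an estimated correlation).

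Other cell lists passed at E12 with few members called. Of 24 Schwann and satellite cell genes, 1 was higher, 3 lower and 20 not called (1 and 5 adjusted over the list alone), with the myelin gene Mal at -3.25 and the factor Pou3f1 at 2.44 (adjusted p = 0.00256, and adjusted p = 0.747 with an estimated correlation). Medians were -0.50 for 22 endothelial and mural genes (1 lower and 21 not called, adjusted p = 0.00256) and -0.33 for 34 mesenchyme genes (all uncalled, adjusted p = 0.023). Proliferation genes had a median of 0.28 (37 of 37 not called, adjusted p = 0.00859), and Insig1 (0.74) stood in a cholesterol synthesis list with a median of 0.35 (2 of 19 higher, adjusted p = 0.000119). With an estimated correlation these 4 lists had adjusted p = 0.747 for endothelium, 0.839 for mesenchyme, 0.839 for proliferation and 0.747 for cholesterol synthesis. The count rests on the spread of all 40 arrays, and the later sorted SG arrays vary more between replicates. With only the 6 arrays compared 6212 genes were called at E12, and 6761 with array weights.

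By E13 more genes were lower than higher in the SG, and 149 of the 268 higher and 238 of the 358 lower genes of E12 were called again the same way. Nwd2, a nucleoside-triphosphatase domain gene, was lower in the SG (log2 -6.06 ± 0.27, adjusted p = 3.91e-17; 5.64 ± 0.22 (SD, n = 3) against 11.71 ± 0.14 (SD, n = 3)). Ngef, the Rho exchange factor that acts below Eph receptors, was lower by 5.36 (adjusted p = 2.43e-12), with Gm16551 (-5.98), Glra2 (-4.80), Kazald1 (-4.80) and Rgs8 (-4.77). Prdm8 (5.17 ± 0.88, adjusted p = 0.000122), the phosphatase inhibitor Ppp1r17 (4.80), Fgf5 (4.59), Neurod6 (4.28), the ubiquitin ligase Rnf152 (4.26) and Mab21l1 (4.10) were higher. Of the 1427 genes called, 346 were higher and 1081 lower. Of 60 oxidative phosphorylation genes, 0 were higher, 19 lower and 41 not called (0 and 27 adjusted over the list alone), with the ATP synthase gene Atp5d at -0.78 (adjusted p = 6.85e-07, and adjusted p = 0.904 with an estimated correlation). Beside that group, the 3-prime to 5-prime difference of the Gapdh control probe sets was 1.96 ± 0.23 in the SG and 2.92 ± 0.10 in the VG (SD, n = 3 each; exact permutation p = 0.1, the smallest that 3 against 3 can give). Of 22 endothelial and mural genes, 0 were higher, 7 lower and 15 not called (0 and 9 adjusted over the list alone), including Rgs5 (-3.56), Abcc9 (-2.40) and Cldn5 (-2.20) (adjusted p = 0.00273, and adjusted p = 0.904 with an estimated correlation). Myo6 (1.80) was higher, and of 9 hair cell genes, 1 was higher, 0 lower and 8 not called (2 and 0 adjusted over the list alone, adjusted p = 0.0079, and adjusted p = 0.0859 with an estimated correlation). Proliferation genes had a median of 0.19, 1 higher and 36 not called (adjusted p = 0.00273, and adjusted p = 0.904 with an estimated correlation). Leaving out SG array 1 gave 683 genes and VG array 1, 2 or 3 gave 786, 944 or 860, with only the 6 arrays compared 5265 were called, and quantile scaling gave 478 higher and 778 lower.

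Guidance receptors and adhesion molecules were split between the ganglia at both early stages rather than shifted as a group. At E12 the ephrin receptors Epha5 (2.85 ± 0.40, adjusted p = 6.77e-06) and Epha3 (1.74), the Slit receptor Robo2 and the netrin Ntn4 (1.18) were higher in the SG. The ligand Efna3 (-2.06 ± 0.32, adjusted p = 3.21e-05) and the semaphorin receptor Plxnc1 (-1.33) were lower. At E13 Epha5 stayed higher (1.94), and the netrin receptor Dcc (-2.51 ± 0.33, adjusted p = 2.47e-06), Plxnb3 (-1.85), Efna3 (-1.62) and Plxnc1 were lower. Of 62 axon guidance genes at E12, 5 were higher, 5 lower and 52 not called (6 and 7 adjusted over the list alone, adjusted p = 0.971, and adjusted p = 0.984 with an estimated correlation). Of the same genes at E13, 4 were higher, 7 lower and 51 not called (4 and 7 adjusted over the list alone, adjusted p = 0.772, and adjusted p = 0.904 with an estimated correlation). The protocadherin Pcdh8 was lower at E12 (-3.26 ± 0.41, adjusted p = 1.61e-06) and E13 (-4.06), as were Pcdh19 (-1.79 and -2.04) and the cadherin Cdh8 (-1.63 and -2.18). The synaptic organiser Lrrtm4 was higher at E12 (2.52), Cdh13 was higher at E13 (2.07), and Lrrtm1 (-3.52) and Pcdh20 (-2.43) were lower at E13. Of 61 adhesion genes at E12, 5 were higher, 6 lower and 50 not called (8 and 11 adjusted over the list alone, adjusted p = 0.171, and adjusted p = 0.839 with an estimated correlation). At E13, 6 were higher, 8 lower and 47 not called (6 and 8 adjusted over the list alone, adjusted p = 0.764, and adjusted p = 0.904 with an estimated correlation).

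Between E12 and E13 the gene sets overlapped far beyond what independent lists give. There were 149 genes higher in the SG at both stages where 6.86 would be met by independence, 238 lower at both where 28.6 would be, and 1 with opposite calls. Of the 149, 43 were still higher at E16, 36 at P0, 29 at P6 and 36 at P15, against 43.2, 37.1, 38.5 and 42.5 for independent lists, and 56, 48, 57 and 54 were by then lower. Of the 238, 112, 87, 91 and 97 were still lower, against 79.7, 50.4, 63.7 and 73.6. The later numbers compare sorted SG neurons with dissected VG tissue.

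At all 6 stages 58 genes were called in the same direction. Chrdl1, a BMP antagonist, Rasgef1b, Dtx1, Efs, Hrc, Trp53i11, Fzd1, Thtpa and Tbc1d9 made up the 9 that were higher in the SG. Chrdl1 differed by 1.44 at E12, 2.39 at E13, 2.74 at E16, 2.94 at P0, 0.52 at P6 and 1.33 at P15. The 49 lower genes include Nwd2, Gm16551, Aldh1a7, Tafa2, Corin, Slc6a11, Vwc2l, Pcdh8, Mal and Cbln4, a cerebellin that organises synapses. Cbln4 differed by -3.01, -4.67, -2.57, -3.17, -3.81 and -3.42 from E12 to P15, and Nwd2 by -3.55, -6.06, -3.90, -3.29, -3.09 and -3.00. The GABA transporter Slc6a11 (-2.12 at E12, -3.71 at P15) and the secreted Tafa2 (-1.76, -4.32) are 2 more. Lists from E16 on share sorting and strain, so the overlap expected of independent lists is no test. Only the arrays compared gave 132 genes, array weights 185 and a 2-fold minimum 24. Each of the 9 higher genes lost a call at some stage under an alternative. Fzd1 was not called at E12, E13, P0 and P15 when probe sets were averaged, and at P6 its value became -0.0576. Calls ended with 1 array left out for Chrdl1 (P6, 0.43 without SG array 2, 0.31 without VG array 1), Rasgef1b (P6, 0.52 to 0.85 without SG array 1 or 2 or VG array 1 or 3) and Dtx1 (P15, 0.36 without SG array 1, 0.66 and 0.71 without VG arrays 1 and 2). The same held for Efs (E13, 0.72 to 0.79 without any of the 6 arrays), Hrc (0.66 at E13 without SG array 1, 0.42 at P0 without VG array 1) and Thtpa (P6, 0.33 to 0.37 without SG array 2 or 4 or VG array 1 or 2). Trp53i11 lost its call at E16 without VG array 2 or 3 (0.40, 0.37) and at P0 without SG array 3 (0.31) or VG array 1 or 2 (0.41, 0.34). Tbc1d9 lost it at E16 without SG array 1 or 4 or VG array 1 or 3 (0.35 to 0.41), at P0 without SG array 1, 2 or 4 or VG array 1 (0.32 to 0.48), at P6 without SG array 4 or VG array 1 or 2 (0.45 to 0.52), and at P15 without SG array 2 (0.31) or VG array 3 (0.34). Among the lower genes named, Corin lost it at P15 without SG array 3 (-1.44) or VG array 2 (-1.48). Mal lost it at P6 without SG array 4 (-1.19) or any VG array (-1.37 to -1.48), and at P15 without SG array 2 (-1.12) or VG array 2 or 3 (-1.37, -1.46).

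At E16 the SG samples are sorted neurons for the first time, and mesenchyme, glial, dividing-cell and erythroid genes were lower than in the VG. Of 27 macrophage genes, 6 were higher, 7 lower and 14 not called (4 and 5 adjusted over the list alone, adjusted p = 0.742, and adjusted p = 0.936 with an estimated correlation). Fmod (-6.24 ± 0.67, adjusted p = 4.7e-09) and Aspn (-5.58), matrix genes of fibroblasts, the myelin gene Mbp (-5.69) and the embryonic globin Hbb-y (-7.06) were lower in the SG, with Cldn1 (-6.40) and Aldh1a1 (-6.31). Podxl2 (4.46 ± 0.43, adjusted p = 6.26e-10), Amer2 (4.46) and Nacad (4.37) were the highest. The count was 8442 genes, 62.4% of all tested, with 3916 higher and 4526 lower. Of 34 mesenchyme genes, 2 were higher, 27 lower and 5 not called (3 and 28 adjusted over the list alone, adjusted p = 6.58e-06, and adjusted p = 0.821 with an estimated correlation). Of 24 Schwann and satellite genes, 2 were higher, 16 lower and 6 not called (2 and 16 adjusted over the list alone), with Fabp7 at -5.17 (adjusted p = 0.000401, and adjusted p = 0.821 with an estimated correlation). Of 37 proliferation genes, 1 was higher, 31 lower and 5 not called (1 and 31 adjusted over the list alone), among them Bub1 (-3.54) (adjusted p = 3.55e-06, and adjusted p = 0.821 with an estimated correlation). Of 13 erythroid genes, 2 were higher, 9 lower and 2 not called (2 and 9 adjusted over the list alone, adjusted p = 0.00483, and adjusted p = 0.661 with an estimated correlation). Guidance genes again moved both ways: of 62 genes, 22 were higher, 17 lower and 23 not called (23 and 17 adjusted over the list alone), with Ntng2 (4.12), Epha10 (3.95) and Sema4g (2.84) higher and Sema3c (-4.15) lower (adjusted p = 0.193, and adjusted p = 0.821 with an estimated correlation). Of the called genes 3673 differed 2-fold or more.

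**Figure D2:**
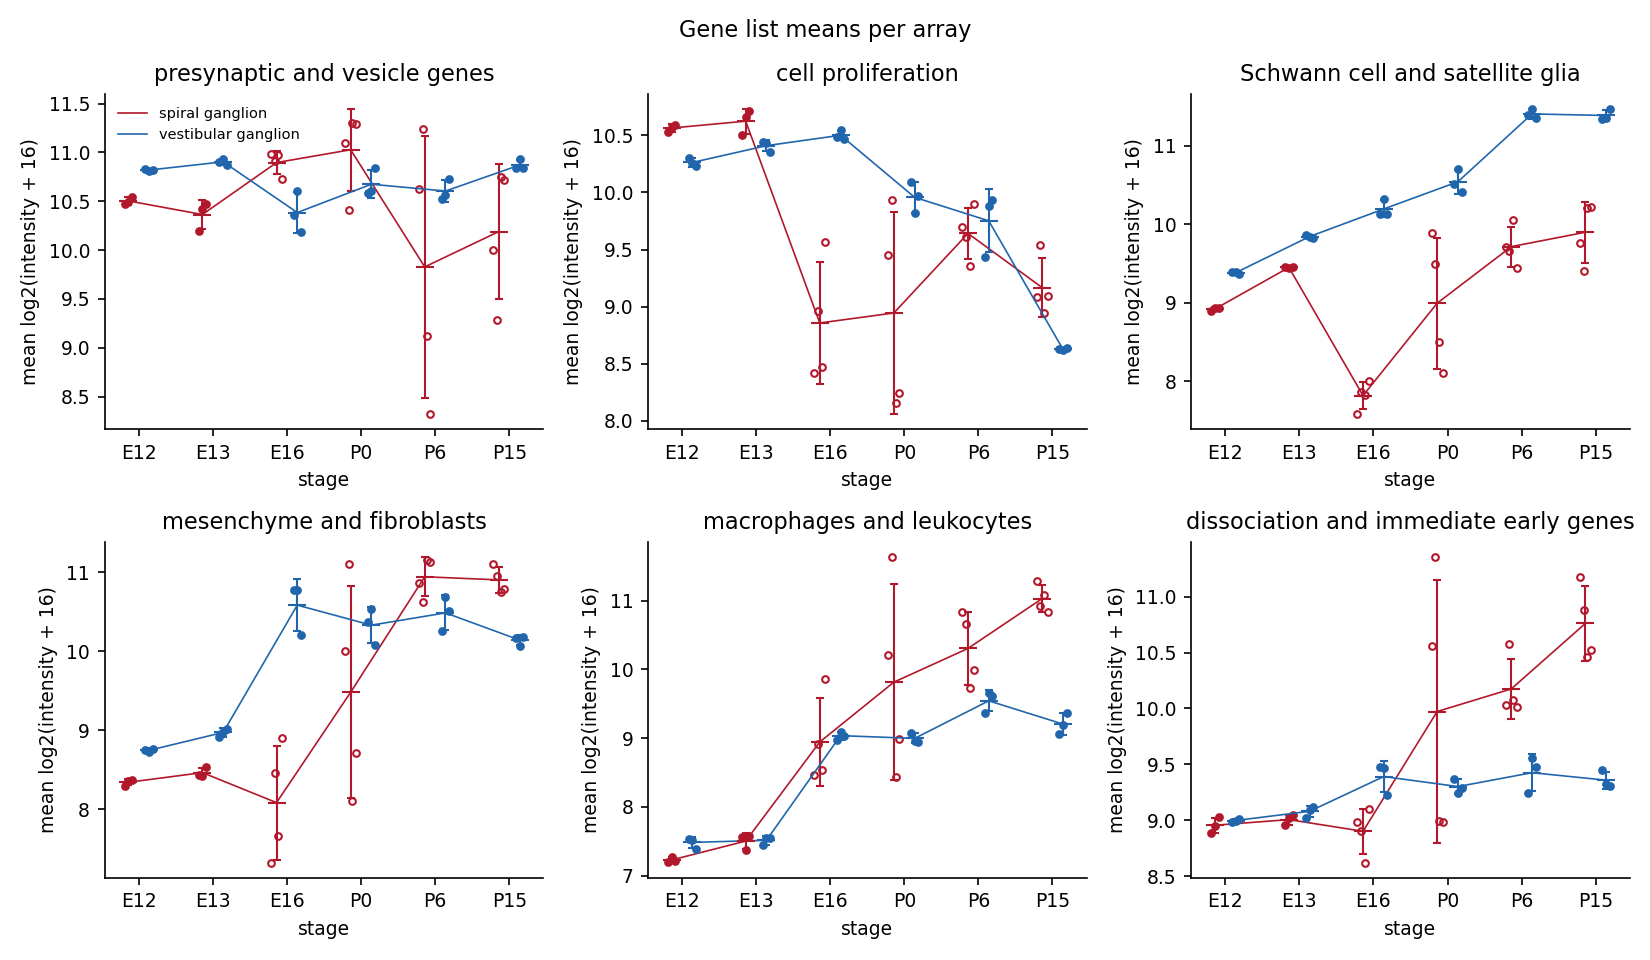
Mean log2 expression of 6 gene lists by stage: points are arrays (open points are sorted SG samples), lines join group means and error bars are SD. The mesenchyme list is lower in sorted SG arrays than in VG arrays at E16, with a median log2 difference of -2.68.

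At P0 the sorted SG samples carried fewer glial and brain transcripts than the VG, and SG arrays 1 and 2 carried more immune and stress transcripts. Cxcl2 (4.92 ± 0.57, adjusted p = 7.96e-08), a neutrophil chemokine, Rgs1 (4.37) and Cpne9 (4.08) were the highest in the SG, and Slc6a20a (-5.39), the neuropeptide gene Crh (-5.15) and Alas2 (-5.37) the lowest. There were 6232 genes called, 3368 higher and 2864 lower. Of 27 macrophage genes, 10 were higher, 0 lower and 17 not called (10 and 0 adjusted over the list alone), and the actin-binding Coro1a was 2.38 (adjusted p = 0.0272, and adjusted p = 0.864 with an estimated correlation). Of 36 dissociation and immediate early genes, 15 were higher, 2 lower and 19 not called (17 and 2 adjusted over the list alone), with Gadd45b at 3.10 (adjusted p = 0.00652, and adjusted p = 0.864 with an estimated correlation). P0 SG array 2 and 2 P6 SG arrays stood apart and were doubted after their values were seen. Without those 3 arrays these medians went from 0.73 to 0.21 for macrophages (camera adjusted p = 0.506) and from 0.73 to 0.35 for immediate early genes (camera adjusted p = 0.167), and neither list was called. Of 24 Schwann and satellite genes, 2 were higher, 20 lower and 2 not called (2 and 20 adjusted over the list alone), with Cdh19 at -3.23 (adjusted p = 1.05e-05, and adjusted p = 0.337 with an estimated correlation). Of 18 brain and hindbrain genes, 1 was higher, 9 lower and 8 not called (1 and 12 adjusted over the list alone), with Olig1 (-4.77), Gad1 (-4.68) and Slc1a3 (-3.98) lower (adjusted p = 0.000979, and adjusted p = 0.326 with an estimated correlation). Median differences were -0.94 for proliferation genes (adjusted p = 1.05e-05), -1.05 for mesenchyme (adjusted p = 0.0241), -0.89 for endothelium (adjusted p = 0.00793) and -0.70 for erythroid genes (adjusted p = 0.00467). With an estimated correlation those 4 had adjusted p = 0.864, 0.864, 0.864 and 0.326. Without the 3 doubted arrays 6976 genes were called, 3621 higher and 3355 lower. Of the 6232 genes 2205 differed 2-fold or more.

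At P6 the SG to VG difference in myelinating cell and synthesis genes was wide. The transcription factor Pou3f1 (-4.24 ± 0.49, adjusted p = 3.89e-08) and the myelin lipid carrier Pmp2 (-4.51) were lower in the SG, next to Sult1e1 (-5.28), Dcdc2a (-5.05) and Olig1 (-5.11). Cby1 (4.71 ± 0.47, adjusted p = 2.34e-09), Rgs1 (4.51) and P3h3 (4.11) were the highest of 7112 called genes, 3496 higher and 3616 lower. The glial list was lower: of 24 members, 1 was higher, 16 lower and 7 not called (1 and 16 adjusted over the list alone, adjusted p = 0.000136, and adjusted p = 0.852 with an estimated correlation). Of 19 cholesterol synthesis genes, 2 were higher, 12 lower and 5 not called (2 and 12 adjusted over the list alone), with Msmo1 (-2.22), Cyp51 (-1.61) and Idi1 (-1.45) lower (adjusted p = 0.0119, and adjusted p = 0.898 with an estimated correlation). Of 40 ribosomal protein genes, 21 were higher, 1 lower and 18 not called (21 and 1 adjusted over the list alone), Rplp0 by 0.97 (adjusted p = 0.00426, and adjusted p = 0.898 with an estimated correlation). Immediate early genes were higher, 18 of 36 with 1 lower, and Atf3 was 3.07 (adjusted p = 0.00426, and adjusted p = 0.898 with an estimated correlation). Macrophage genes had 9 higher and 1 lower, with Ccl3 at 3.09 (adjusted p = 0.0417, and adjusted p = 0.898 with an estimated correlation). Brain genes had 2 higher and 9 lower, with Gad1 at -4.18 (adjusted p = 0.0228, and adjusted p = 0.852 with an estimated correlation). Without the 3 doubted arrays 6864 genes were called, 3504 higher and 3360 lower. Of the 7112 genes 2580 differed 2-fold or more.

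By P15 immune and stress genes were higher in the SG, and lipid and energy genes were higher in the VG. Ccl3, a macrophage chemokine, was higher in the SG (log2 5.40 ± 0.75, adjusted p = 4.45e-07), with Sfrp2 (5.65) and Rgs1 (5.65). Sult1e1 (-6.53 ± 0.36, adjusted p = 5.34e-15), the proton channel Otop1 (-5.39) and the vesicle protein Synpr (-5.37) were lower. Of 8041 genes called, 3859 were higher and 4182 lower. Of 27 macrophage genes, 20 were higher, 0 lower and 7 not called (20 and 0 adjusted over the list alone, adjusted p = 8.9e-06, and adjusted p = 0.776 with an estimated correlation). Of 36 dissociation and immediate early genes, 24 were higher, 1 lower and 11 not called (24 and 1 adjusted over the list alone), Socs3 by 3.67 (adjusted p = 1.61e-06, and adjusted p = 0.776 with an estimated correlation). Cholesterol synthesis genes were lower: of 19, 1 was higher, 16 lower and 2 not called (1 and 17 adjusted over the list alone), with Sqle at -2.21 (adjusted p = 3.25e-05, and adjusted p = 0.687 with an estimated correlation). Of 60 oxidative phosphorylation genes, 8 were higher, 30 lower and 22 not called (8 and 30 adjusted over the list alone), with Cox7c at -2.39 (adjusted p = 0.0316, and adjusted p = 0.876 with an estimated correlation). Of 40 ribosomal protein genes, 27 were higher, 3 lower and 10 not called (27 and 3 adjusted over the list alone), with Rps14 at 1.61 (adjusted p = 8.9e-06, and adjusted p = 0.687 with an estimated correlation). Adhesion genes leaned to the VG: of 61, 9 were higher, 25 lower and 27 not called (9 and 25 adjusted over the list alone), with Pcdh11x (-3.44), Chl1 (-3.39) and Lrrtm4 (-3.04) lower (adjusted p = 0.0316, and adjusted p = 0.776 with an estimated correlation). Schwann and satellite genes were lower in 17 of 24 and higher in 0 (adjusted p = 0.000196, and adjusted p = 0.687 with an estimated correlation). Mesenchyme genes were higher in 13 of 34 and lower in 1, with Prrx2 at 3.15 (adjusted p = 0.0316, and adjusted p = 0.876 with an estimated correlation). Of the called genes 3157 differed 2-fold or more.

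**Figure D3:**
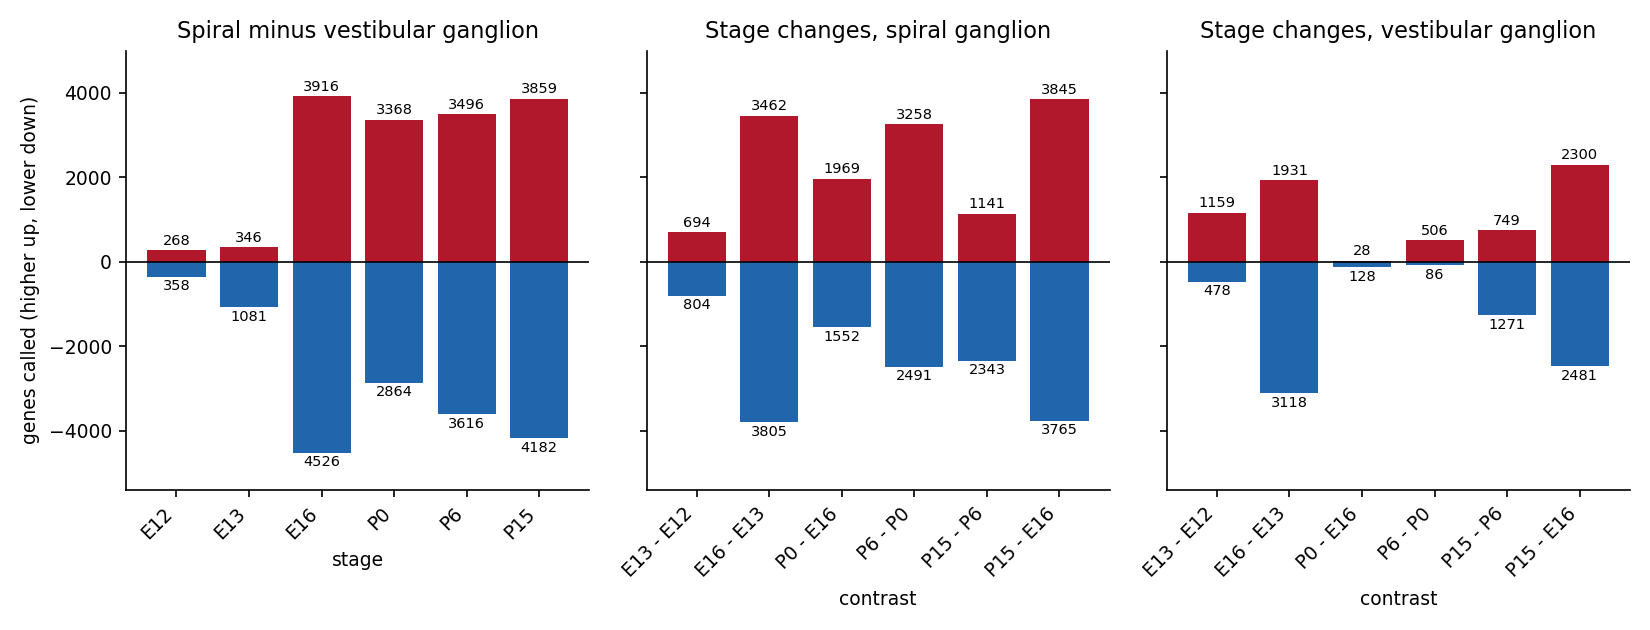
Number of genes called in each comparison, as bars above 0 for higher and below 0 for lower: SG minus VG at 6 stages, then stage changes in the SG and in the VG. The VG changed in 156 genes from E16 to P0 where the SG changed in 3521.

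The changes of the ganglia from E12 to E13 overlapped. Neurog1, the bHLH factor that starts otic neuron formation, fell by 3.10 ± 0.46 in the SG (adjusted p = 3.13e-05) and by 3.03 ± 0.46 in the VG (adjusted p = 3.53e-05). In the SG, Clec14a (3.76), Tecrl (2.94) and Mbp (1.95) rose, and Mpzl2 (-3.63), the ligand Efna5 (-1.69) and the adhesion genes Flrt1 (-2.22) and Ncam2 (-1.78) fell. In the VG, the retinoic acid enzyme Aldh1a1 (3.31), Trhr (2.62), Mlip (2.53), the netrin receptor Unc5d (1.86) and Plxnb3 (1.68) rose, and Ppp1r14a (-3.10) and Vegfd (-3.04) fell. The SG changed in 1498 genes (694 up, 804 down) and the VG in 1637 (1159 up, 478 down). There were 397 genes that rose in both (59.5 for independent lists), 266 that fell in both (28.4) and 1 with opposite calls. Across genes, which are not independent replicates, the 2 changes had r = 0.687. Of 19 cholesterol synthesis genes in the SG, 0 were higher, 5 lower and 14 not called (0 and 8 adjusted over the list alone), with Dhcr7 at -1.07 (adjusted p = 1.4e-05, and adjusted p = 0.775 with an estimated correlation). Of 60 oxidative phosphorylation genes, 1 was higher, 13 lower and 46 not called (3 and 18 adjusted over the list alone), with Atp5l at -1.45 (adjusted p = 0.0119, and adjusted p = 0.926 with an estimated correlation). Of 40 ribosomal protein genes, 0 were higher, 7 lower and 33 not called (0 and 8 adjusted over the list alone, adjusted p = 0.0192, and adjusted p = 0.926 with an estimated correlation). Schwann and satellite genes had a median of 0.45 in the SG, 3 higher and 21 not called (adjusted p = 0.00361, and adjusted p = 0.926 with an estimated correlation). In the VG, of 21 neuron identity genes, 0 were higher, 5 lower and 16 not called (0 and 5 adjusted over the list alone, adjusted p = 0.000705, and adjusted p = 0.451 with an estimated correlation). Beside them, of 24 Schwann and satellite genes, 5 were higher, 0 lower and 19 not called (5 and 0 adjusted over the list alone, adjusted p = 0.231, and adjusted p = 0.987 with an estimated correlation). Leaving out E12 array 1, 2 or 3 or E13 array 1 or 2 gave 764 to 961 SG genes, the lowest without E13 array 1, and leaving out any of the 6 VG arrays 827 to 1032. With only the 6 arrays compared 5637 and 8079 genes were called in the SG and VG, and quantile scaling split the SG genes as 1180 up and 507 down.

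In the fit of all 40 arrays few genes were called as changing differently between the ganglia from E12 to E13. Vegfd, a lymphatic growth factor, differed by 2.32 ± 0.41 (adjusted p = 0.00636), falling more in the VG, and Scel by 2.05. Gm16551 (-2.57) and Nwd2 (-2.52 ± 0.38, adjusted p = 0.000579) moved the other way, so the SG deficit of Nwd2 widened. There were 20 such genes, 9 higher and 11 lower, a count the splits below cannot test. Of 19 cholesterol synthesis genes, 0 were higher, 1 lower and 18 not called (0 and 3 adjusted over the list alone, median -0.53, adjusted p = 7.7e-07). Ribosomal protein genes (-0.20, adjusted p = 6.99e-06) and oxidative phosphorylation genes (-0.20, adjusted p = 7.7e-07) had lower medians with 0 members called. The Gapdh control difference also fell, from 2.97 to 1.96 in the SG and 3.04 to 2.92 in the VG. Macrophage genes had a median of 0.21 (adjusted p = 0.00392) and neuron identity genes -0.01, above the -0.0795 of all genes (adjusted p = 0.0159). With an estimated correlation adjusted p was 0.473, 0.619, 0.719, 0.784 and 0.719. With array weights 1907 genes were called, with only the 12 arrays compared 2638, without the 3 doubted arrays 57, and with any of the 12 arrays left out 6 to 12.

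From E13 to E16 dividing-cell and glial genes fell in the SG as sampling went from dissected tissue to sorted neurons. Dlg2, a postsynaptic scaffold gene, rose by 4.81 ± 0.52 (adjusted p = 1.04e-08), with P4ha3 (5.89) and Aplnr (4.50), and Hbb-y (-7.77), the homeobox gene Dlx1 (-5.93) and Ppp1r17 (-5.82) fell. The SG changed in 7267 genes, 53.7% of all tested, with 3462 up and 3805 down. Of 37 proliferation genes, 1 was higher, 31 lower and 5 not called (1 and 31 adjusted over the list alone), with Cenpf at -3.26 (adjusted p = 3.2e-09, and adjusted p = 0.928 with an estimated correlation). Of 24 glial genes, 3 were higher, 12 lower and 9 not called (3 and 12 adjusted over the list alone), with Foxd3 at -4.65 (adjusted p = 0.0148, and adjusted p = 0.928 with an estimated correlation). Channel genes rose: of 38, 17 were higher, 3 lower and 18 not called (17 and 3 adjusted over the list alone), with the potassium channels Kcnq3 (2.96) and Kcnh2 (2.76) (adjusted p = 0.0363, and adjusted p = 0.928 with an estimated correlation). Macrophage genes rose beside them: of 27, 17 were higher, 0 lower and 10 not called (19 and 0 adjusted over the list alone), with C1qb at 3.68 (adjusted p = 0.000226, and adjusted p = 0.928 with an estimated correlation). Guidance genes went both ways, 23 up and 14 down of 62, with Epha10 (3.63) and Ntng2 (2.72) up and Sema3c (-4.08) down (adjusted p = 0.414, and adjusted p = 0.928 with an estimated correlation). Of the called genes 2802 changed 2-fold or more.

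In the VG the same interval brought genes of connective tissue, epithelium and blood-borne cells. Fmod rose by 6.59 ± 0.72 (adjusted p = 4.32e-08) with Ogn (5.95), Mpzl2 (6.17) and the gap-junction gene Gjb6 (4.82), and Galnt15 (-4.58), Rnasek (-4.24) and Nacad (-3.51) fell. Of 5049 genes called, 1931 rose and 3118 fell. Of 34 mesenchyme genes, 17 were higher, 0 lower and 17 not called (20 and 0 adjusted over the list alone, adjusted p = 2.97e-08, and adjusted p = 0.676 with an estimated correlation). Of 27 macrophage genes, 16 were higher, 1 lower and 10 not called (17 and 1 adjusted over the list alone), with Cd163 at 5.18 (adjusted p = 5.17e-07, and adjusted p = 0.72 with an estimated correlation). Of 22 endothelial and mural genes, 11 were higher, 0 lower and 11 not called (11 and 0 adjusted over the list alone), with Acta2 at 3.34 (adjusted p = 0.000333, and adjusted p = 0.72 with an estimated correlation). Of 21 otic epithelium genes, 8 were higher, 0 lower and 13 not called (8 and 0 adjusted over the list alone, adjusted p = 0.000333, and adjusted p = 0.571 with an estimated correlation). By the labels the E13 VG is whole and the E16 VG is its inferior part. Quantile scaling gave 2319 up and 2483 down, and array weights 7866 genes.

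From E16 to P0, stage and added trypsin together, respiratory-chain genes and markers of other cells rose in the sorted SG. Calb2, the calcium buffer calretinin, rose by 4.40 ± 0.62 (adjusted p = 5.05e-06), with Cxcl2 (4.97) and Mbp (4.42), while Dpf1 (-2.93), the calcium pump Atp2b4 (-2.92), Ntng2 (-2.41) and the axon guidance gene Draxin (-1.60) fell. Of 3521 genes, 1969 rose and 1552 fell. Of 60 oxidative phosphorylation genes, 35 were higher, 0 lower and 25 not called (41 and 0 adjusted over the list alone), with Ndufa5 at 0.97 (adjusted p = 2.95e-13, and adjusted p = 0.811 with an estimated correlation). Beside them, of 34 mesenchyme genes, 21 were higher, 1 lower and 12 not called (23 and 1 adjusted over the list alone, median 1.48, adjusted p = 7.25e-08, and adjusted p = 0.811 with an estimated correlation). Of 36 dissociation and immediate early genes, 18 were higher, 0 lower and 18 not called (22 and 1 adjusted over the list alone, adjusted p = 2.95e-06, and 0.811 with an estimated correlation). Schwann and satellite genes rose in 11 of 24 with 0 falling, Fabp7 by 3.23 (adjusted p = 0.000195, and 0.811 with an estimated correlation). Ribosomal protein genes rose in 11 of 40 and fell in 0 (adjusted p = 0.00411, and 0.811 with an estimated correlation). Macrophage genes rose in 8 of 27 and fell in 0 (adjusted p = 0.00323, and 0.943 with an estimated correlation). Without the 3 doubted arrays 3405 genes were called (1823 up, 1582 down), the mesenchyme median was 0.87 and that of immediate early genes 0.52. In that fit the ribosomal (limma camera adjusted p = 0.0626) and macrophage lists (median 0.14, adjusted p = 0.449) were not called. Of the 3521 genes 737 changed 2-fold or more, and with only the 8 arrays compared 1313 were called.

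From P0 to P6 genes of young neurons fell in the sorted SG samples as matrix and vessel genes rose. Insm1, a zinc-finger factor of new neurons, fell by 4.94 ± 0.63 (adjusted p = 6.85e-07), as did the intermediate filament gene Prph (-4.91), Vgf (-4.85), Dcx (-4.10), the sodium channel Scn9a (-3.88) and the calcium channel Cacna1b (-3.29). Dmp1 (6.17 ± 0.42, adjusted p = 1.36e-11) and Ibsp, bone matrix genes, rose with Vit (6.14). Of 5749 genes, 3258 rose and 2491 fell. Of 35 presynaptic genes, 0 were higher, 25 lower and 10 not called (0 and 28 adjusted over the list alone, median -1.20, adjusted p = 2.13e-07, and adjusted p = 0.493 with an estimated correlation). Of 21 neuron identity genes, 1 was higher, 13 lower and 7 not called (1 and 13 adjusted over the list alone, adjusted p = 0.000145, and adjusted p = 0.493 with an estimated correlation). Of 38 channel genes, 2 were higher, 18 lower and 18 not called (2 and 18 adjusted over the list alone, adjusted p = 7.03e-05, and adjusted p = 0.493 with an estimated correlation). Beside these, of 34 mesenchyme genes, 23 were higher, 2 lower and 9 not called (25 and 2 adjusted over the list alone, adjusted p = 7.03e-05, and adjusted p = 0.493 with an estimated correlation). Of 22 endothelial and mural genes, 16 were higher, 0 lower and 6 not called (19 and 1 adjusted over the list alone), with Ets1 at 2.68 (adjusted p = 2.75e-06, and adjusted p = 0.493 with an estimated correlation). P6 SG arrays 3 and 4 have the lowest neuronal gene means of their group. Without the 3 doubted arrays the medians were -0.24 for presynaptic genes, -0.45 for neuron identity and -0.23 for channels, 2.04 for mesenchyme and 2.03 for endothelium, with 4246 genes called, 2816 up and 1430 down. The guidance, adhesion, type I and type II lists lost their calls in that fit. In other splits of these 8 arrays 6561 genes were reached, more than the 5749, when P0 array 2 and P6 array 2 changed places, and with only these 8 arrays 1231 genes were called.

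From P6 to P15 some erythroid, immune and stress genes rose in the sorted SG and some adhesion genes fell. Hemgn, a gene of blood precursors, rose by 4.85 ± 0.43 (adjusted p = 1.39e-09), with Slc4a1 (4.09) and Chil3 (4.18), and Nell1 (-5.67 ± 0.38, adjusted p = 4.41e-12), Pgm5 (-4.41), Car8 (-4.28), Chl1 (-3.35), Cntn4 (-2.61), Dcc (-1.70) and Sema3d (-2.06) fell. There were 3484 genes, 1141 up and 2343 down. Of 13 erythroid genes, 7 were higher, 1 lower and 5 not called (7 and 2 adjusted over the list alone, adjusted p = 3.89e-05, and adjusted p = 0.0765 with an estimated correlation). Of 61 adhesion genes, 3 were higher, 18 lower and 40 not called (3 and 21 adjusted over the list alone, adjusted p = 0.0264, and adjusted p = 0.616 with an estimated correlation). Immediate early genes rose in 11 of 36 and fell in 0, Gadd45g by 1.34 (adjusted p = 1.1e-05, and adjusted p = 0.616 with an estimated correlation). Macrophage genes rose in 4 of 27 and fell in 0 (adjusted p = 0.00011, and 0.616 with an estimated correlation). Type II neuron markers rose in 6 of 11 and fell in 0, with Cilp at 3.71 (adjusted p = 0.000182, and adjusted p = 0.133 with an estimated correlation). Type I markers had a median of 0.83 (adjusted p = 0.0105, and adjusted p = 0.616 with an estimated correlation). Presynaptic genes had a median of 0.36, 3 higher, 2 lower and 30 not called (adjusted p = 0.0328, and adjusted p = 0.763 with an estimated correlation). Without the 3 doubted arrays the presynaptic median turned to -0.5127 and the type I median to -0.4394, and the type II median was 0.23. That fit called 2418 genes, 720 up and 1698 down, and the fit of only these 8 arrays called 607.

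From E16 to P15, with trypsin added from P0, the neuronal lists below fell in the sorted SG and glial and connective tissue lists rose. Each was called only with the preset correlation. Gap43, the growth-cone protein, fell by 3.94 ± 0.36 (adjusted p = 1.53e-10), with Dcx (-5.28), Insm1 (-6.30), Vgf (-5.70), Synpr (-5.54), Slc8a2 (-5.41) and Zcchc12 (-5.40). Scn4b (4.79 ± 0.46, adjusted p = 4.19e-10), a sodium channel subunit, and Syt2 (3.02), the fast synaptotagmin, rose. So did Mmp13 (7.51 ± 0.64, adjusted p = 4.51e-11), Fabp4 (7.21), Fmod (7.03), Dmp1 (6.75), Ibsp (6.68) and Wif1 (6.49), which belong to bone, fat and matrix cells. In total 7610 genes changed, 3845 up and 3765 down. Of 62 axon guidance genes, 14 were higher, 29 lower and 19 not called (15 and 29 adjusted over the list alone), with Efna3 (-3.62) and Epha5 (-3.50) down and Sema5a (3.35) up (adjusted p = 0.0141, and adjusted p = 0.457 with an estimated correlation). Of 61 adhesion genes, 9 were higher, 27 lower and 25 not called (9 and 28 adjusted over the list alone, adjusted p = 0.00783, and adjusted p = 0.457 with an estimated correlation). Of 38 channel genes, 6 were higher, 19 lower and 13 not called (6 and 20 adjusted over the list alone), with Cacna1h (-4.37) and Scn9a (-4.22) down (adjusted p = 0.0141, and adjusted p = 0.594 with an estimated correlation). Of 33 glutamate receptor and postsynaptic genes, 2 were higher, 15 lower and 16 not called (2 and 15 adjusted over the list alone), with Grik2 (-2.33) and Homer1 (-1.91) down (adjusted p = 0.0489, and adjusted p = 0.457 with an estimated correlation). Of 35 presynaptic genes, 4 were higher, 13 lower and 18 not called (4 and 13 adjusted over the list alone, adjusted p = 0.0489, and adjusted p = 0.813 with an estimated correlation). Of 21 neuron identity genes, 2 were higher, 12 lower and 7 not called (2 and 12 adjusted over the list alone, adjusted p = 0.00345, and adjusted p = 0.457 with an estimated correlation).

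Beside each of those neuronal groups, markers of other cells rose in the same SG arrays. Of 34 mesenchyme genes, 28 were higher, 1 lower and 5 not called (29 and 1 adjusted over the list alone), with Aspn at 6.33 (median 3.05, adjusted p = 6.54e-10, and adjusted p = 0.457 with an estimated correlation). Of 27 macrophage genes, 25 were higher, 0 lower and 2 not called (25 and 0 adjusted over the list alone), with Cd14 at 4.38 (adjusted p = 2.48e-07, and adjusted p = 0.457 with an estimated correlation). Schwann and satellite genes rose in 17 of 24 and fell in 2, Mbp by 6.27 (adjusted p = 1.54e-05, and adjusted p = 0.457 with an estimated correlation). Endothelial and mural genes rose in 12 of 22 and fell in 0, Pdgfrb by 5.05 (adjusted p = 0.000291, and adjusted p = 0.457 with an estimated correlation). Of 36 immediate early genes, 26 were higher, 1 lower and 9 not called (26 and 1 adjusted over the list alone), with Gadd45b at 5.21 (adjusted p = 2.13e-07, and adjusted p = 0.457 with an estimated correlation). Erythroid genes rose in 8 of 13 and fell in 1 (adjusted p = 0.00345, and adjusted p = 0.457 with an estimated correlation). Otic epithelium genes rose in 9 of 21 and fell in 2, Gjb6 by 5.81 (adjusted p = 0.0489, and adjusted p = 0.457 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 60 and fell in 2, with Cox7c (-1.30) down and Ndufa6 (0.79) up (adjusted p = 0.0141, and adjusted p = 0.726 with an estimated correlation).

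The VG, dissected at every stage, changed little from E16 to P0. Crh, the stress neuropeptide gene, rose by 3.23 ± 0.44 (adjusted p = 6.93e-05), and the RNA-binding Igf2bp1 fell by 2.24 ± 0.37 (adjusted p = 0.00109). Hbb-y (-3.76) was the lowest gene of 156, 28 up and 128 down, though it was not called with only the 6 arrays compared. Of 13 erythroid genes, 0 were higher, 2 lower and 11 not called (0 and 7 adjusted over the list alone, median -0.65, adjusted p = 6.2e-06, and adjusted p = 0.0461 with an estimated correlation), the only list in any comparison to hold with an estimated correlation. Proliferation genes had a median of -0.51, 1 lower and 36 not called (adjusted p = 1.28e-06, and adjusted p = 0.83 with an estimated correlation). Medians rose with 0 members called for presynaptic (0.27, adjusted p = 0.000395), Schwann (0.34, adjusted p = 7.04e-05), brain (0.22, adjusted p = 0.00282) and oxidative phosphorylation genes (0.10, adjusted p = 3.1e-07). With an estimated correlation those 4 had adjusted p = 0.979, 0.542, 0.39 and 0.83. The number of genes was 51 without P0 array 2, 61 without P0 array 3, 238 without P0 array 1, 97 and 54 without E16 arrays 1 and 2, 21 with only the 6 arrays compared, 350 without the doubted SG arrays and 1567 with array weights.

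Myelin genes rose in the VG from P0 to P6, and dividing-cell genes fell from P6 to P15. Mobp (3.84 ± 0.29, adjusted p = 9.83e-11), Pmp2 (3.13) and Mag (2.39), all myelin genes, rose with the hair cell factor Gfi1 (4.30), Ermn (4.22) and Otog (2.83), and Stk32b fell by 2.23. From P0 to P6, 592 genes were called, 506 up and 86 down. Schwann and satellite genes moved with them: of 24, 7 were higher, 0 lower and 17 not called (10 and 0 adjusted over the list alone, adjusted p = 9.99e-06, and adjusted p = 0.443 with an estimated correlation). Medians were -0.35 for neuron identity (adjusted p = 0.000138), 0.41 for cholesterol synthesis (adjusted p = 0.0065), 0.47 for otic epithelium (adjusted p = 0.0144), -0.19 for proliferation (adjusted p = 0.000805) and -0.06 for ribosomal genes, with 0.0773 for all genes (adjusted p = 0.00111). Their adjusted p with an estimated correlation ran 0.443, 0.69, 0.69, 0.738 and 0.69. From P6 to P15, Bub1 fell by 2.33 ± 0.47 (adjusted p = 0.00108), with Nusap1 (-2.10), Ccnb2 (-2.01), the neuropeptide Nts (-3.58), Stfa3 (-4.02) and Sema6a (-1.47), and Cyp4f14 (3.17), Il31ra (3.06) and Myh8 (2.83) rose. That step changed 2020 genes, 749 up and 1271 down. Of 37 proliferation genes, 0 were higher, 23 lower and 14 not called (0 and 27 adjusted over the list alone, adjusted p = 1.34e-12, and adjusted p = 0.621 with an estimated correlation). Of 40 ribosomal protein genes, 0 were higher, 17 lower and 23 not called (0 and 24 adjusted over the list alone), with Rps14 at -0.92 (adjusted p = 5.27e-11, and adjusted p = 0.377 with an estimated correlation). Otic epithelium (-0.76, adjusted p = 0.0352, and adjusted p = 0.649 with an estimated correlation) and brain genes (-0.39, adjusted p = 0.0352, and adjusted p = 0.621 with an estimated correlation) had lower medians. Leaving out P0 array 3 gave 244 genes for P0 to P6 (316 without P0 array 2, 326 and 316 without P6 arrays 1 and 2) and leaving out P6 array 3 gave 1079 for P6 to P15 (1105 and 1202 without P15 arrays 1 and 2), and array weights gave 2781 and 5694.

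Over E16 to P15 mitotic genes fell and myelin genes rose in the VG. Bub1b, a mitotic checkpoint gene, fell by 4.07 ± 0.83 (adjusted p = 0.000272), and Calb2 rose by 5.06 ± 0.72 (adjusted p = 2.34e-06) with Sult1e1 (5.19), Ceacam10 (5.00), Tesc (4.90), Gm13629 (4.75) and Smpx (4.71). Hbb-y (-6.60), Stk32b (-4.85), Insm1 (-4.48), Nts (-4.42) and Myh3 (-4.06) fell. Of 4781 genes, 2300 rose and 2481 fell. Of 37 proliferation genes, 1 was higher, 34 lower and 2 not called (1 and 34 adjusted over the list alone, adjusted p = 1.19e-17, and adjusted p = 0.281 with an estimated correlation). Of 24 Schwann and satellite genes, 14 were higher, 0 lower and 10 not called (15 and 1 adjusted over the list alone), with Pmp2 (4.11) and Fa2h (3.74) up (adjusted p = 2.51e-06, and adjusted p = 0.281 with an estimated correlation). Of 40 ribosomal protein genes, 0 were higher, 25 lower and 15 not called (0 and 27 adjusted over the list alone), with Rpl35 at -0.85 (adjusted p = 4.64e-09, and adjusted p = 0.281 with an estimated correlation). Of 19 cholesterol synthesis genes, 8 were higher, 2 lower and 9 not called (8 and 2 adjusted over the list alone), with Fdps at 1.41 (adjusted p = 0.014, and adjusted p = 0.669 with an estimated correlation). Oxidative phosphorylation genes rose in 18 of 60 and fell in 1, Atp5b by 1.59 (adjusted p = 0.000227, and adjusted p = 0.733 with an estimated correlation). Erythroid genes fell in 7 of 13 and rose in 1 (adjusted p = 0.0183, and adjusted p = 0.378 with an estimated correlation). Neuron identity genes fell in 9 of 21 and rose in 1, with Dcx (-3.66) and Ebf3 (-2.57) (adjusted p = 0.014, and adjusted p = 0.643 with an estimated correlation). Among guidance and adhesion genes, Efna3 (-2.68), Dcc (-2.27) and Pcdh8 (-2.64) fell as Sema5a (2.91) rose.

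The sorted SG and the dissected VG shared some of their E16 to P15 changes and differed in many. Insm1, Dcx, Efna3 and Sema5a moved the same way in both, while Sult1e1 (-5.48 ± 0.51, adjusted p = 1.96e-09), Insyn2b (-5.45) and Pou3f1 (-5.34) changed lower in the SG than in the VG. Fabp4 (9.45 ± 0.81, adjusted p = 6.05e-10), Sfrp2 (8.08) and Aspn (7.79) changed higher. There were 867 genes that rose in both (654 for independent lists), 1006 that fell in both (691) and 742 with opposite calls, and r across genes, which are not independent, was 0.195. The difference was called for 6225 genes, 3222 higher and 3003 lower. Of 35 presynaptic genes, 1 was higher, 11 lower and 23 not called (1 and 11 adjusted over the list alone), with Sncg at -2.83 (adjusted p = 0.0017, and adjusted p = 0.584 with an estimated correlation). Of 38 channel genes, 2 were higher, 14 lower and 22 not called (2 and 13 adjusted over the list alone), with Kcnc2 at -3.57 (adjusted p = 0.0171, and adjusted p = 0.572 with an estimated correlation). Of 19 cholesterol synthesis genes, 0 were higher, 12 lower and 7 not called (0 and 12 adjusted over the list alone, adjusted p = 0.000707, and adjusted p = 0.515 with an estimated correlation). Of 37 proliferation genes, 34 were higher, 1 lower and 2 not called (34 and 1 adjusted over the list alone), with Bub1b at 5.19 (adjusted p = 1.48e-11, and adjusted p = 0.426 with an estimated correlation). Mesenchyme (3.34; 30 of 34 higher, adjusted p = 1.48e-11, and adjusted p = 0.426 with an estimated correlation) and erythroid genes (2.08; 9 of 13 higher, adjusted p = 5.07e-06, and adjusted p = 0.0513 with an estimated correlation) moved beside these. Other medians were 1.93 for macrophages (adjusted p = 3.09e-05), 1.46 for endothelium (adjusted p = 0.00013), 1.60 for immediate early genes (adjusted p = 9.73e-08) and 0.43 for ribosomal genes (adjusted p = 2.03e-06). With an estimated correlation those 4 had adjusted p = 0.572, 0.557, 0.515 and 0.426. Of the called differences 3479 were 2-fold or more, and the ganglia differ here in sorting, trypsin and strain as well as origin.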

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

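The tests of other cells, trypsin, the spread at P0 and the gate below were chosen only after the results were seen; the scaling test, the comparison of the early ganglia and the splits of the arrays were set earlier. The opening kind of result is an array far from the other 3 of its group: 8 of 108 tests (23 list means and 4 array measures in each of 4 groups) gave one, all list means, and chance gives about 1 in 20. At E16 they are SG array 4 for growth factor signalling (9.53, the others 9.47 to 9.48) and hair cell genes (7.63), and array 3 for type II markers (8.88). At P0, SG array 2 stands out for glutamate receptors (8.79), channels (9.60) and oxidative phosphorylation (11.9), and array 3 for hair cell genes (8.05). At P6 it is SG array 2 for immediate early genes (10.6, the others 10.0 to 10.1).

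Another kind is a change that differs between the ganglia, tested as an interaction. From E12 to E13, 20 genes differed, among them Ppp1r17 (2.40), Vegfd (2.32), Scel (2.05), Ccbe1 (-2.68), Gm16551 (-2.57) and Nwd2 (-2.52). List medians differed for neuron identity (-0.0082, above the -0.0795 of all genes), macrophages (0.21), oxidative phosphorylation (-0.20), ribosomal proteins (-0.20) and cholesterol synthesis (-0.53), with 1 member called in all and none of the lists called with an estimated correlation (adjusted p = 0.473 to 0.784). From E16 to P15, 6225 genes differed, among them Fabp4 (9.45), Sfrp2 (8.08), Aspn (7.79), Sult1e1 (-5.48), Insyn2b (-5.45) and Pou3f1 (-5.34). List medians differed for presynaptic genes (-1.06), channels (-0.91), proliferation (1.89), mesenchyme (3.34), endothelium (1.46), macrophages (1.93), erythroid genes (2.08), immediate early genes (1.60), ribosomal proteins (0.43) and cholesterol synthesis (-0.71), none called with an estimated correlation (adjusted p = 0.0513 for erythroid genes and 0.426 to 0.584 for the others). The last kind is signal outside the named genes: of the tested probe sets without 1 gene symbol, 186 differed between the ganglia at E12 and 310 at E13, and 1278 changed from E12 to E13 in the SG and 1375 in the VG.

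Mesenchyme genes rose in the sorted SG arrays from E16 to P15, by a median of 3.05, and differed between arrays of the same sort. Scaling is argued against, since the median was still 2.97 under the scaling that gave the lower value. Over 16 sorted arrays, deviations from stage means of the mesenchyme and presynaptic lists had r = -0.400 (permutation p = 0.00025, adjusted 5e-04; rho = -0.603, p = 0.00053; r = -0.359 without P0 arrays 2 and 3), so other cells in the sorted fraction may account for part of the rise. The 4 array means inside P0 range over 3.00, but arrays of 1 stage cannot test stage, so this excludes nothing. A change of the neurons themselves with age remains open and was not tested apart from the cells sorted with them.

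Dissociation and immediate early genes were higher in sorted SG arrays than in the VG at P6 and P15. At P0 only SG arrays 1 and 2 were above the VG arrays, and the list median went from 0.73 to 0.35, uncalled, without the 3 doubted arrays. Trypsin stays open: 2 sorted P0 arrays lie below all P0 VG arrays, but the list's SG minus VG median was -0.34 (uncalled) at E16, before trypsin. The list followed the macrophage list over the 16 sorted arrays (r = 0.864, permutation p = 0.00507, adjusted 0.00507; rho = 0.709, p = 0.0326; r = 0.650 without P0 arrays 2 and 3), so other cells in the sorted fraction may carry part of it. A ganglion difference stays open: the dissected ganglia gave at most -0.0884 at E12 and E13, and later stages confound ganglion with sorting.

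Macrophage and mesenchyme genes did not move together against the VG. Their difference in the sorted SG against the VG was 2.40 at E16, 1.67 at P0, 0.305 at P6 and 1.06 at P15 (exact permutation p = 0.0286, 0.0286, 0.457 and 0.0286, where 0.0286 is the smallest possible; adjusted 0.0381, 0.0381, 0.457 and 0.0381). In 14 of 16 sorted arrays the macrophage minus mesenchyme mean stood above every VG array of the stage, and the macrophage mean alone did in 11 (1 of 4 at E16, 2 at P0, 4 at P6 and 4 at P15). So macrophages taken by the gate are a candidate explanation, as Mafb is also a macrophage gene. Cells in the proportions of the dissected VG cannot be told apart from this: 3 of 4 stages differed by over 0.5, but the cochlea and the VG need not hold the same tissue around their neurons. No biological explanation could be tested for it.

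Other splits of the arrays tested whether chance gives as many genes, the real one included. Chance is excluded (1 of 35 splits unless given) for SG minus VG at E16 (8442 genes against at most 7226), P0 (6232 against 5608), P6 (7112 against 5458) and P15 (8041 against 6347). The same share was met in the SG for E16 minus E13 (7267 against 6782), P0 minus E16 (3521 against 2027) and P15 minus E16 (7610 against 4136). For the 58 genes of all stages (1 of 100, at most 0) chance stays open, as other E12 or E13 splits alone called 0 genes. It is not excluded for P6 minus P0 in the SG (2 of 35; 5749 against 6561 when P0 array 2 and P6 array 2 changed places), P15 minus P6 in the SG (2 of 35; 3484 against 3853 with P6 array 2 changed) or the E13 minus E12 difference (8 of 100; 20 against 458). That split regroups 2 of 3 SG arrays and no VG array, so the stage change both ganglia share enters it. Such splits cannot test that difference.

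With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 626 and 0 for SG minus VG at E12, 1427 and 0 at E13, and 1498 and 0 for E13 minus E12 in the SG (1 of 10 each). In the VG they were 1637 and 0 for E13 minus E12, 5049 and 0 for E16 minus E13, 156 and 22 for P0 minus E16, 592 and 27 for P6 minus P0, 2020 and 24 for P15 minus P6, and 4781 and 0 for P15 minus E16.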

How the results depend on the processing

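The fit without 3 sorted SG arrays (P0 array 2, P6 arrays 3 and 4) was chosen only after the data were seen; the other alternatives were planned. Counts within 1.5 times those reported are left out below, the cause of a change was not tested unless named, and no offset, trend, filter-free or probe-set alternative moved a count of genes by more. The order of ganglia and stages is SG minus VG from E12 to P15, then SG and VG stage changes.

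With only the arrays compared, 6212 genes were called at E12, 5265 at E13, 5637 for E13 minus E12 in the SG and 8079 in the VG, 2638 for the difference of these changes, 3726 for P15 minus P6 in the VG and 132 at all 6 stages. Counts fell to 1313, 1231 and 607 for the SG steps E16 to P0, P0 to P6 and P6 to P15, and to 21 for E16 to P0 in the VG. By construction this fit takes the spread from the compared arrays, and the sorted ones vary more. Array weights gave 6761 and 4383 at E12 and E13, 5138 for E13 minus E12 and 7147 for P0 minus E16 in the SG, 8116, 7866, 1567, 2781, 5694 and 7431 for the VG steps in order and P15 minus E16, 1907 for the E13 minus E12 difference and 185 at all 6 stages.

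A 2-fold minimum left 366, 519, 3673, 2205, 2580 and 3157 genes for SG minus VG by stage, 372, 2802, 737, 2023, 865 and 3140 for the SG steps and P15 minus E16, 341, 1760, 55, 232, 478 and 1525 in the VG, 3479 for the P15 minus E16 difference and 24 at all 6 stages. The filter at the 75th percentile left 1025, 81 and 1250 genes for E13 minus E12, P0 minus E16 and P15 minus P6 in the VG. Quantile scaling gave 99 genes for P0 minus E16 in the VG, 36 higher and 63 lower. It also changed the split of higher and lower to 478 and 778 at E13, 1180 and 507 for E13 minus E12 in the SG, 1468 and 1948 for P15 minus P6 in the SG, 2319 and 2483 for E16 minus E13 in the VG and 288 and 221 for P6 minus P0 in the VG. Centring changed it to 1073 and 479 for E13 minus E12 in the SG, 2840 and 1077 for P0 minus E16 in the SG and 1807 and 302 for E13 minus E12 in the VG. The median of all genes moved from 0.00 to 0.11 with quantile scaling for E13 minus E12 in the SG.

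Leaving out each array in turn gave 683 (without E13 SG array 1) to 1256 genes at E13, 764 (E13 SG array 1) to 1219 (E13 SG array 3) for E13 minus E12 in the SG, 827 (E13 VG array 1) to 1032 (E13 VG array 2) in the VG and 6 (E12 SG array 1) to 12 (E13 SG array 1) for their difference. In the VG it gave 51 (P0 array 2) to 238 (P0 array 1) for P0 minus E16, 244 (P0 array 3) to 594 for P6 minus P0 and 1079 (P6 array 3) to 1822 for P15 minus P6. Without the 3 sorted arrays 350 genes were called for P0 minus E16 and 1143 for P6 minus P0 in the VG, and 57 for the E13 minus E12 difference.

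Signs turned in few results. The mean over probe sets gave Fzd1 at P6 as -0.0576. Leaving out probe sets that can bind several transcripts gave -0.1666 for Cacna1d (SG, E16 minus E13), -0.3367 for Uqcrq (SG, P0 minus E16) and 0.07307 (P6 minus P0), -0.1574 for Mcm3 (SG, P6 minus P0) and 0.09583 for Rps24 (VG, P15 minus P6). Without the 3 sorted arrays, P15 minus P6 in the SG gave -0.2583 for Snap25, -0.004452 for Syngr1, -0.256 for Ngfr, -0.5127 for the presynaptic list and -0.4394 for the type I list.

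A replicate block changed no count by more than 1.5 times, with 671 genes at E12 and 118 for P0 minus E16 in the VG as examples. Deviations of same-numbered arrays correlated at a median of 0.0476 over 18 pairs within stages (-0.273 to 0.350) and -0.0243 over 96 pairs within ganglia (-0.601 to 0.532), and 8 of 18 VG arrays correlated best with their own number, so the numbers do not pair arrays. Of 723 called results for named genes, 508 kept their call under each alternative run on them (replicate blocks and the stricter filter were not run on all), 99 lost it with an array left out, 100 with only the arrays compared and 82 by the 2-fold minimum. Of the list results, 133 lost the call with an estimated correlation. SG minus VG counts from E16 to P15 and the P15 minus E16 counts of the SG held within 1.5 times under all alternatives but the 2-fold minimum.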

Other observations

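All tests of this part were set before their results were seen except the reading of probe sets without a gene symbol and the fit without 3 arrays, which were chosen after. Of 36 growth factor and neurotrophin genes, 6 were higher, 6 lower and 24 not called (8 and 7 adjusted over the list alone) in SG minus VG at E12 (adjusted p = 0.939, and adjusted p = 0.984 with an estimated correlation), and in the SG from E16 to P15, 19 were higher, 7 lower and 10 not called (19 and 7 adjusted over the list alone, adjusted p = 0.0768, and adjusted p = 0.474 with an estimated correlation). From P6 to P15 in the SG the list median was 0.21 (7 higher, 2 lower, adjusted p = 0.0275, and adjusted p = 0.616 with an estimated correlation), with the receptor gene Bmpr1b falling (-1.65). Glutamate receptor and postsynaptic genes at E12 included 2 higher and 5 lower of 33 (adjusted p = 0.0544, and adjusted p = 0.747 with an estimated correlation). From P0 to P6 in the SG 5 rose, the metabotropic receptor Grm3 by 2.99, and 13 fell (adjusted p = 0.0459, and adjusted p = 0.493 with an estimated correlation).

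Neuron subtype lists were not called in the SG from E16 to P15, although both were called lower from P0 to P6 (adjusted p = 0.00615 and 0.0226, and 0.493 and 0.493 with an estimated correlation) and higher from P6 to P15 (0.0105 and 0.000182, and 0.616 and 0.133). Without the 3 doubted arrays the P0 to P6 calls ended and the type I median from P6 to P15 was -0.4394. Of 17 type I markers in the SG from E16 to P15, 4 were higher, 5 lower and 8 not called (4 and 5 adjusted over the list alone, adjusted p = 0.707, and adjusted p = 0.912 with an estimated correlation), and of 11 type II markers, 3 were higher, 3 lower and 5 not called (3 and 3 adjusted over the list alone, adjusted p = 0.765, and adjusted p = 0.912 with an estimated correlation). Between the ganglia at P15 type II markers had a median of 0.96 (6 higher, 2 lower, adjusted p = 0.108, and adjusted p = 0.776 with an estimated correlation). Of 23 transcription factors of the ganglia, 12 were higher and 1 lower in the difference of P15 minus E16, a list not called (adjusted p = 0.0921, and adjusted p = 0.572 with an estimated correlation). Hair cell genes were tested for 9 members: in the VG from E16 to P15 3 rose and 1 fell (adjusted p = 0.269, and adjusted p = 0.644 with an estimated correlation).

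Probe sets without 1 gene symbol changed mostly downward from E12 to E13 in both ganglia: of 5055 tested, 263 rose and 1015 fell in the SG and 312 rose and 1063 fell in the VG. Named genes split 694 and 804 in the SG and 1159 and 478 in the VG over the same step. The 3-prime to 5-prime difference of Gapdh at E13 was 1.96 in the SG and 2.92 in the VG (adjusted p = 0.24 over 12 tests of 2 controls, where the exact p of 0.1 is the smallest that 3 against 3 can give).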
